A study of Mus musculus with 9 samples.

How the data were processed

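RNA was measured in single mouse oocytes at metaphase II, 1 oocyte per Affymetrix Mouse Gene 1.0 ST array. Per the labels' protocols, females of the outbred ICR strain, 2 months old, received 10 IU of PMSG and, 46 hours later, 10 IU of hCG, and between 1 and 3 cells were taken from each of 3 mice per condition. RNA was purified with the Qiagen RNeasy Mini kit or the Arcturus PicoPure kit, or the oocyte was lysed in the NuGEN direct lysis buffer and used as a crude lysate. All 9 samples were amplified with the NuGEN Ovation One-Direct kit (Ribo-SPIA) and biotinylated. The groups were taken from the sample titles, with 3 oocytes in each. The labels do not say which oocyte came from which mouse, so the p-values measure the spread between these oocytes, some of which may share a mouse. The protocol also mentions fertilized embryos, which were not analysed here.

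The deposited table holds 1 log2 expression value per row and array, 35556 rows by 9 arrays with 0 missing values. GCOS, Affymetrix Expression Console and GCRMA are named, without versions or order, in the submitters' processing notes. The scale is not stated in the sources used here. It was read as log2 from the values, which ran from 2.41 to 13.90 with array medians between 7.12 and 7.24. No scanner files were used, so the normalization and background correction could not be repeated, and their effect on low values is not known. The number of arrays limits the precision. The genome build is not given in the sources used here, and no coordinates are printed.

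Rows were named through the platform's probe table: 21789 rows had 1 gene symbol, 1621 had several and 12146 had none. Only rows with 1 symbol were named. Of these, 21698 matched the RefSeq gene table (GRCm38.p6) by Entrez identifier, which changed 0 symbols. Where a gene had more than 1 row (999 genes), the row with the highest mean over the 9 arrays was used, which left 19938 genes. No filter on level and no new normalization were applied. The background of each array was set at the 95th percentile of its 1246 olfactory, vomeronasal and taste receptor genes, whose mean over the arrays was 7.29. A gene was called detected on an array when it lay above that array's level. This level is a working limit and not a detection p-value.

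Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) in 1 fit over all 9 arrays with 3 groups and 6 residual degrees of freedom. The contrasts were crude lysate against the mean of both purified groups, PicoPure against RNeasy, direct lysis against each kit, and a moderated F over the 3 preparations. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are given on the log2 scale with their standard errors. Counts of detected genes and the spread of each array were compared by permutation tests of the one-way F statistic over all 1680 assignments of the arrays. The test is exact for the counts. For the spread, the statistic was computed on each array's median absolute deviation from its group mean, a statistic chosen when the test was carried out. The 3 values of a group share that mean, so the test of the spread is only approximate. In a simulation on the same 19938 genes, limma recovered 84% of genes changed by 1 log2 unit between crude lysate and purified RNA and 97% of those changed by 2. Between PicoPure and RNeasy it recovered 81% and 95%. With 200 genes changed in each simulation, there were 11 and 12 false calls. The simulation drew independent normal noise with the variances estimated by the fit, so recovery in the real arrays may be lower.

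The 18 gene lists covered oocyte-specific and maternal effect genes, meiotic cell cycle and spindle genes, maternal mRNAs recruited for translation with mRNA decay factors, cumulus and granulosa cell genes, blood and immune cell genes, oviduct genes, mitochondrially encoded genes, ribosomal protein genes, nuclear-encoded respiratory chain genes, proteasome genes, small nuclear and nucleolar RNA genes, microRNA precursor genes, histone genes, sensory receptor genes, keratin, skin and milk protein genes, immediate early and heat shock genes, reference genes and zygotic genome activation genes. They were tested with limma's camera at a preset correlation of 0.01, adjusted over 36 tests (18 lists and 2 contrasts), again with an estimated correlation, and with fry. The lists, the contrasts, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, for crude lysate against purified RNA and for PicoPure against RNeasy, the 10 largest differences in each direction among genes past the threshold whose arrays did not overlap between the sides and whose higher side lay above background. It also took up to 4 members of each list described, those with the smallest p above background, and a fixed panel of oocyte genes. For both pairwise contrasts of direct lysis it took counts and genes already named. Where the lower side was not above background on any array, a fold is given as a lower limit, computed against the background level of those arrays.

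The alternatives were a filter on level, every row as a feature, the mean of a gene's rows, a further quantile normalization, median centring, values raised to the background level, trended and robust variances, array weights, the replicate number as a block, a minimum 2-fold difference, only the arrays of the groups compared, other detection levels, another measure of spread, and each array left out in turn. Fitting the purified samples as 1 group was added after seeing the data. Level-matched random lists (10000 draws), shuffles and random splits used fixed seeds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.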

Results

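Gene expression was measured in 9 single metaphase II oocytes of ICR mice on whole-transcript arrays, with 3 oocytes for each of 3 ways of preparing the RNA. In 6 of the oocytes the RNA was purified on columns, 3 with RNeasy and 3 with PicoPure. The other 3 were lysed directly and their crude lysate was amplified. The values were the authors' normalized log2 expression values, with array medians between 7.12 and 7.24. The design compares how the preparation affects the transcriptome read from 1 cell.

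All preparations showed the transcripts of a mature oocyte. Of 51 oocyte-specific and maternal effect genes, 49 lay above background on all 9 arrays, and their median level was 11.99 against a background level of 7.29. Bmp15, an oocyte growth factor, had 12.90 ± 0.04 (SD, n = 3) in crude lysate and 12.84 ± 0.01 (SD, n = 6) in purified RNA. Its relative Gdf9 had 12.66 ± 0.03 and 12.70 ± 0.05. The zona pellucida genes Zp1, Zp2 and Zp3 had 12.36, 12.20 and 11.56 in crude lysate and 12.11, 12.22 and 11.65 in purified RNA. The maternal effect genes Nlrp5, Npm2 and Dppa3 had 12.66, 12.69 and 12.32 in crude lysate and 12.59, 12.64 and 12.28 in purified RNA. Btg4, an adaptor of maternal mRNA decay, had 12.24 and 12.46. Mos, the kinase that holds the oocyte at metaphase II, had 9.99 ± 0.56 in crude lysate and 10.04 ± 0.29 in purified RNA. The cytoskeletal gene Actb lay between 10.77 and 11.30 in crude lysate and between 10.86 and 11.14 in purified RNA. None of these 11 panel genes passed the test between crude lysate and purified RNA or between both kits. Gapdh, the remaining panel gene, had no row named for it alone.

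Markers of cumulus, granulosa, blood and immune cells were mostly low, and oviduct genes less so. Of 38 cumulus and granulosa cell genes, 7 lay above background on all 9 arrays and 22 on none. The highest were Rgs2, at 12.48 in crude lysate and 12.43 in purified RNA, and Bmpr1b, at 11.25 and 11.39. Of 21 blood and immune cell genes, 3 lay above background on all arrays and 15 on none. Of 22 oviduct genes the numbers were 10 and 7. No member of these 3 lists passed the test in either comparison, and none of the lists was called as a whole.

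The number of detected genes was 10156 ± 554 (SD, n = 3) with RNeasy, 11037 ± 60.5 (SD, n = 3) with PicoPure and 11108 ± 390 (SD, n = 3) with direct lysis. The difference among the 3 preparations did not pass a threshold of 0.05 (exact permutation test over 1680 assignments, p = 0.0643, where the smallest possible is 0.00357). Each RNeasy count (9640 to 10741) lay below each PicoPure count (10987 to 11104), while the direct lysis counts (10679 to 11441) overlapped both. The permutation p was 0.0286 without RNeasy replicate 2, 0.0392 without direct lysis replicate 2 and 0.0321 with the 99th percentile of the receptors as background. It was 0.182 with their 90th percentile and 0.557 with the median of all genes as the level, where direct lysis exceeded RNeasy by 76.3 genes instead of 952. The counts depend on each array's own background level, which was 7.27 to 7.48 with RNeasy, 7.19 to 7.26 with PicoPure and 7.23 to 7.28 with direct lysis. They therefore do not separate lower sensitivity with RNeasy from a higher background. In all, 8589 of 19938 genes (43.1%) lay above background on every array and 7000 on none.

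**Figure D1:**
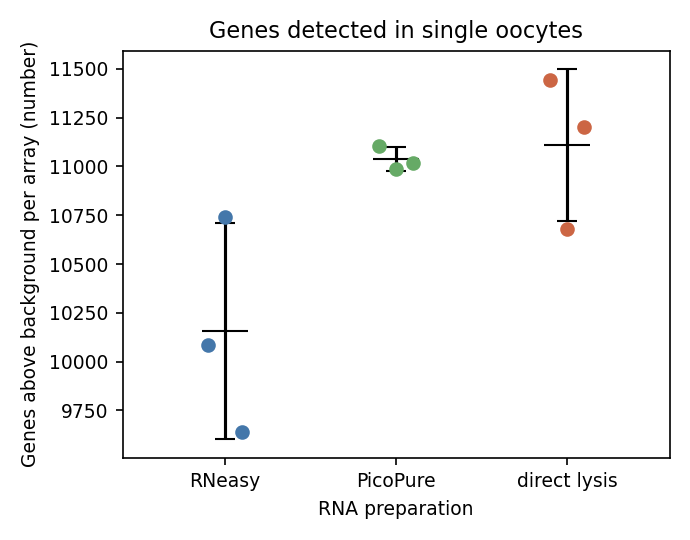
Number of genes above the background level (vertical axis, not starting at 0) on each of the 9 arrays, by RNA preparation (horizontal axis). Points are single oocytes, horizontal bars are means and error bars are the SD of 3 oocytes. The RNeasy oocytes lay between 9640 and 10741, the PicoPure oocytes between 10987 and 11104, and the direct lysis oocytes between 10679 and 11441.

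Replicate oocytes were most alike with PicoPure. Across genes, which are not independent replicates, Pearson's r between replicates was 0.977 to 0.981 with PicoPure, 0.969 to 0.978 with RNeasy and 0.968 to 0.973 with direct lysis. The median over genes of the SD of 3 oocytes was 0.108 log2 units with PicoPure, 0.126 with RNeasy and 0.146 with direct lysis. For the arrays' median deviations from their group mean, the permutation test among preparations gave p = 0.0464. The permutation p was 0.0107 with the filter on level and 0.00714 with a further quantile normalization or median centring. With values raised to background, or with the mean absolute difference between replicates, it was 0.00357. The 3 deviations of a group share its mean and are not independent, so each p is approximate and may be too small. Without direct lysis replicate 1, 2 or 3 the permutation p was 0.339, 0.382 or 0.25. The difference in median SD between direct lysis and PicoPure went from 0.0377 to 0.00997, -0.00219 or 0.0155. With 2 oocytes left, both the SD and the deviations of direct lysis are smaller by construction. These values therefore do not show whether the difference depends on 1 lysate.

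Crude lysate and purified RNA differ in the lysis buffer as well as in the column step, and may differ in the mice used. Their comparison therefore does not isolate column purification. In crude lysate 133 genes were lower and 68 were higher (201 of 19938 genes, limma, adjusted p under the threshold). The lower genes were mostly well expressed: 127 lay above background in purified RNA, 121 also in crude lysate, and 57 differed by at least 2-fold. Cks2, a subunit of cyclin-dependent kinases needed for meiosis, was 12.3-fold lower, with 8.37 ± 0.85 (SD, n = 3) in crude lysate and 11.93 to 12.08 (range, n = 6) in purified RNA (difference -3.63 ± 0.31 SE, adjusted p = 0.00504). All of its 3 rows were lower, by -3.45 to -3.77. Dcun1d5, which promotes cullin neddylation, was 6.98-fold lower (8.72 ± 0.46 against 11.52 ± 0.08, adjusted p = 0.00236). Leprot, an endosomal membrane protein gene, was not above background in any crude lysate and was at least 6.95-fold lower (adjusted p = 0.0152). Il7, a cytokine gene, was 3.85-fold lower (8.93 ± 0.19 against 10.87 ± 0.22, adjusted p = 0.00236), and Gmcl1, the mouse germ cell-less gene, 4.99-fold lower (adjusted p = 0.0108).

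The other genes with the largest decreases were Armcx5, the RNA polymerase II phosphatase gene Ssu72 (-2.53), the oocyte-expressed Tcl1b4 (-2.40) and the mitochondrial translocase gene Timm21 (-2.03). Armcx5 averaged 6.70 in crude lysate, below the background level, and its difference was -2.15 with values raised to background. Cnot8, a deadenylase subunit, differed by -2.79 ± 0.49 SE, but its crude lysates spread widely (8.99 ± 1.34, SD, n = 3), its adjusted p was 0.0488, and its second row, at -1.56, had an adjusted p of 0.0605. Genes higher in crude lysate were mostly weakly expressed. Their median difference was 0.55, against -0.93 for the lower genes. Only 50 of the 68 lay above background in crude lysate, and 33 were above background on no purified array. Of the 133 lower genes, 9 were above background on no crude lysate. The median differences of the higher and lower genes are therefore not directly comparable. Try5, a trypsin gene, had 8.55 ± 0.29 in crude lysate against 7.44 ± 0.11 in purified RNA (2.15-fold, adjusted p = 0.0152). Sox1, a neural transcription factor gene, had 9.01 ± 0.19 against 8.03 ± 0.14 (1.97-fold, adjusted p = 0.0152). Adam34l averaged 6.70 in purified RNA, below the background level, and was higher in crude lysate by 1.03 with values raised to background. The noncoding 5730408K05Rik was higher by 1.00. Olfr1029, an olfactory receptor gene, was at least 1.61-fold higher, Gm13629 at least 1.20-fold and the D-amino acid oxidase gene Dao at least 1.19-fold, since none was above background in purified RNA. With values raised to background, Gm13629 and Dao did not pass (adjusted p = 0.236 and 0.104), nor did Cnot8 (0.0517). Over 18 or 19 alternatives for each gene, the call of Cks2, Dcun1d5, Il7 and Olfr1029 was lost in 0, of Gmcl1 and Leprot in 1, of Try5 and Sox1 in 2, of Timm21 in 3, of Armcx5 in 4, of Ssu72 and 5730408K05Rik in 6 and of Adam34l in 8. It was lost in 10 for Tcl1b4, Gm13629 and Dao and in 12 for Cnot8, mostly with single arrays left out.

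**Figure D2:**
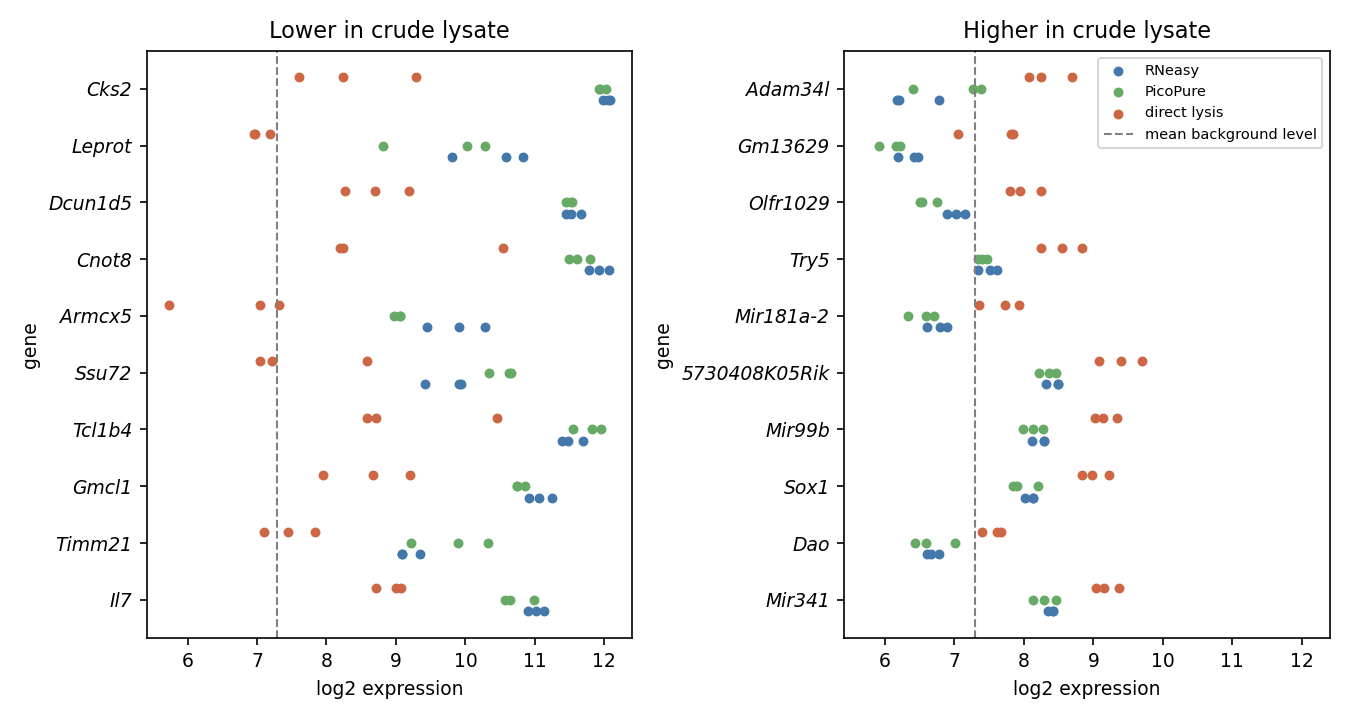
Log2 expression (horizontal axis) of the 10 named genes lower and the 10 higher in crude lysate (vertical axis), 1 point per oocyte and 3 oocytes per preparation. The dashed line is the mean background level of 7.29. Cks2 lay at 7.61 to 9.29 in the crude lysates and at 11.93 to 12.08 in purified RNA.

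The count fell when any purified array was left out. It was 24, 67 and 111 without RNeasy replicates 1, 2 and 3, and 61, 43 and 116 without PicoPure replicates 1, 2 and 3. At an unadjusted p under 0.05 there were 2830 genes with all arrays and between 2400 and 2730 in these 6 fits. Under a further quantile normalization 75 genes were higher and 83 lower, so that the share of higher genes moved from 33.8% to 47.5%.

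By gene list, the smallest p for crude lysate belonged to maternal mRNAs recruited for translation and mRNA decay factors. Of 36 members 4 were lower and 0 higher (7 lower adjusted over the list alone), and 27 had a negative difference (camera, adjusted p = 5.3e-04; adjusted p = 0.144 with an estimated correlation). Tent2, a cytoplasmic poly(A) polymerase gene, was lower by -1.58 ± 0.20 SE, and its second row by -1.09. Plat, a classic dormant maternal mRNA that encodes tissue plasminogen activator, was lower by -0.36 ± 0.06, and the deadenylase gene Cnot7 by -0.36 ± 0.06 (adjusted p = 0.0488). Cnot8 was the fourth. The median of the list was -0.08, and -0.01 under a further quantile normalization, where the list was not called. The meiotic, respiratory chain and ribosomal protein lists were not called there either.

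Of 52 meiotic cell cycle and spindle genes 3 were lower and 0 higher (4 lower adjusted over the list alone; camera, adjusted p = 0.0134; adjusted p = 0.144 with an estimated correlation). They were Cks2, Fbxo43 (-1.01 ± 0.15 SE), whose product keeps the anaphase-promoting complex inhibited at metaphase II, and Cdc20 (-1.13 ± 0.18), an activator of that complex. Birc5, a chromosomal passenger gene, differed by -0.29 with an adjusted p of 0.0805. The median of this list was -0.06, and 0.03 under a further quantile normalization. It was -0.10 against PicoPure and -0.01 against RNeasy, where 25 members were positive and 27 negative. Among 51 oocyte-specific genes, Omt2a alone passed over all genes (-0.92 ± 0.16, adjusted p = 0.0456; 1 higher and 3 lower adjusted over the list alone), and the list was not called (adjusted p = 0.302). Zp1, Accsl and Oosp1, next by p, had differences of 0.25, -0.52 and -0.26.

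Of 78 nuclear-encoded respiratory chain genes 2 were lower, Cox6b1 (-1.05 ± 0.18 SE) of complex IV and Atp5j of the ATP synthase, with 8.19 in crude lysate and 9.20 in purified RNA (adjusted p = 0.0494) (3 lower adjusted over the list alone). The list was called at an adjusted p of 0.0043, with an adjusted p of 0.184 with an estimated correlation. Uqcrfs1, not past the threshold, had -0.76. Cox8c, also not past it, was above background in no crude lysate and was at least 1.15-fold lower. The median of the list was -0.23 against RNeasy and -0.07 against PicoPure. Of 62 ribosomal protein genes 1 was lower, Rpl32l, which lay below background on both sides (1 higher and 3 lower adjusted over the list alone; camera, adjusted p = 0.0247; adjusted p = 0.548 with an estimated correlation). Rps25, Rpl24 and Rpl7a had differences of -0.81, -0.94 and -0.42, and Rpl29 of 0.35, none past the threshold. The median of the ribosomal list was -0.35 against RNeasy and 0.03 against PicoPure, where 32 of 62 members were positive. Ribosomal protein genes have many near-identical copies, and their rows can share signal.

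Of 300 microRNA precursor genes 10 were higher and 2 lower in crude lysate (19 and 4 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.224). Mir99b had 9.17 ± 0.16 in crude lysate and 8.18 ± 0.12 in purified RNA, Mir341 9.19 ± 0.17 and 8.35 ± 0.12, and Mir598 11.06 ± 0.23 and 10.42 ± 0.13. Mir181a-2 was at least 1.29-fold higher, but did not pass with values raised to background (adjusted p = 0.19). Over the alternatives, the call was lost in 0 of 19 for Mir99b, 3 of 19 for Mir341 and 9 of 18 for Mir181a-2. Mir598 did not keep its call in every alternative either. The other members past the threshold lay below background on both sides. The 1246 sensory receptor genes, used as background, had a median difference of -0.04 (1 higher and 2 lower; 1 and 1 adjusted over the list alone; camera, adjusted p = 0.0481; adjusted p = 0.723 with an estimated correlation). Their median was -0.09 against RNeasy and 0.02 against PicoPure. Among them Vmn2r-ps104 was lower by -0.98 ± 0.08 SE.

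No gene passed in the remaining lists, and none was called. Rn7sk, a 7SK RNA gene, had -0.37 in the row used, but its second row had -0.63 with an adjusted p of 0.0153 over all rows. The adjusted camera p was 0.145 for cumulus and granulosa genes, 0.933 for blood and immune genes, 0.341 for oviduct genes and 0.306 for the 2 mitochondrially encoded genes with a row of their own (ND3 and COX2). It was 0.605 for 39 proteasome genes, 0.734 for 65 small nuclear and nucleolar RNA genes, 0.538 for 27 histone genes and 0.145 for 136 keratin, skin and milk protein genes. It was 0.124 for 30 immediate early and heat shock genes, 0.955 for 17 reference genes and 0.627 for 23 zygotic genome activation genes. Adjusted over the list alone, 1 histone gene was lower and 1 immediate early gene higher. For the reference genes the median was -0.01 and the mean -0.04 while camera pointed up, for the proteasome the median was 0.00 and the mean -0.07, and for blood genes the median was 0.01 and the mean -0.02. Of 16 alternatives, the call for crude lysate was lost in 2 for maternal mRNAs (quantile normalization and an estimated correlation), 5 for the respiratory chain, 6 for meiotic genes and 9 each for ribosomal protein genes and receptors. All but the maternal list were lost with the filter on level and without direct lysis replicate 3. The ribosomal list was also lost with median centring, values raised to background and fry, and without PicoPure replicate 1 or direct lysis replicate 2. The meiotic list was also lost without RNeasy replicate 2 or PicoPure replicate 1, the respiratory list with fry, and the receptors with values raised to background and fry, among others, and without RNeasy replicate 3, PicoPure replicate 2 or direct lysis replicate 1. Among the list members named, the call was lost in 5 of 19 alternatives for Tent2, 9 for Fbxo43, 10 for Cdc20, Omt2a and Cox6b1, 11 for Plat, 13 for Atp5j and 14 for Cnot7. The list calls were weak as a set, since 32 of 100 splits of the arrays gave at least 5 called lists. The number called was 3 without PicoPure replicate 1 and 1 without direct lysis replicate 3.

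PicoPure against RNeasy compares both column kits. With PicoPure 8 genes were higher and 4 lower (12 of 19938 genes, limma). Nicn1 was higher by 1.52 ± 0.15 SE (9.24 ± 0.29 against 7.71 ± 0.16, SD, n = 3 each, adjusted p = 0.0207). Cherp, a calcium homeostasis gene of the endoplasmic reticulum, was higher by 1.23 ± 0.11 and Exoc1, an exocyst subunit gene, by 1.21 ± 0.09 (adjusted p = 0.0165 and 0.0163). The RNA helicase gene Ddx39a, the chromatin remodelling gene Mta1, Wdr44 and the calcium pump gene Atp2b3 were higher by 0.95, 0.90, 0.82 and 0.80. Nfatc2ip was not above background with RNeasy and was at least 1.38-fold higher with PicoPure. The largest decrease was in n-R5s136, a 5S ribosomal RNA gene, with 8.44 ± 0.21 against 10.31 ± 0.29 (3.66-fold, adjusted p = 0.0165). Fth1, the ferritin heavy chain gene, was lower by -0.99 ± 0.10, the ubiquitin-conjugating enzyme gene Ube2b by -0.76 ± 0.08 and the cobalamin gene Mmadhc by -0.72 ± 0.07 (adjusted p = 0.0207 for each).

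This count was fragile: at an unadjusted p under 0.05 there were 1591 genes, and limma called 0 with trended and robust variances, 0 with only the 6 arrays of both kits and 51 with array weights. It was 0, 4 and 4 without RNeasy replicates 1, 2 and 3, 1, 0 and 0 without PicoPure replicates 1, 2 and 3, and 6 without direct lysis replicate 1. The share of higher genes was 66.7%, and 54.5% under a further quantile normalization.

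Several gene groups differed together between both kits, although none of their members passed over all genes. Of 62 ribosomal protein genes 52 had a lower value with PicoPure, with a median difference of -0.33 (camera, adjusted p = 3.2e-07; adjusted p = 0.144 with an estimated correlation; 4 lower adjusted over the list alone). Rps9 had 7.75 ± 0.13 (SD, n = 3) with PicoPure and 10.85 ± 0.54 (SD, n = 3) with RNeasy, a difference of -3.10 ± 0.43 SE with an adjusted p of 0.0928, and its second row had -1.65. Rps4x differed by -1.27 ± 0.16 (adjusted p = 0.0673), Rps10 by -0.66 and Rplp1 by -0.53. Of 27 histone genes 24 had a lower value, with a median of -0.16 (adjusted p = 1.4e-05; adjusted p = 0.144 with an estimated correlation; 4 lower adjusted over the list alone). H2bc18 differed by -1.40, H1f1 by -0.51, H4c9 by -0.50 and H2bc1 by -1.53. Of the 27 histone genes 12 lay above background on all arrays, and their list median was -0.32 with values raised to background. Of 78 respiratory chain genes 61 had a lower value, with a median of -0.27 (adjusted p = 5.6e-04; adjusted p = 0.144 with an estimated correlation; 1 lower adjusted over the list alone). Atp5j2 differed by -0.66 ± 0.08 (adjusted p = 0.0665), Atp5j by -0.80, Cox8c by -0.45 and Ndufa10 by 0.41. The call of the respiratory chain list was lost without RNeasy replicate 2. The direction of these medians was the same under quantile normalization, median centring and values raised to background. Direct lysis lay nearer to PicoPure than to RNeasy in these lists. Its histone median was -0.16 against RNeasy and 0.06 against PicoPure. The 10 splits of the 6 purified arrays are too few to exclude chance.

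**Figure D3:**
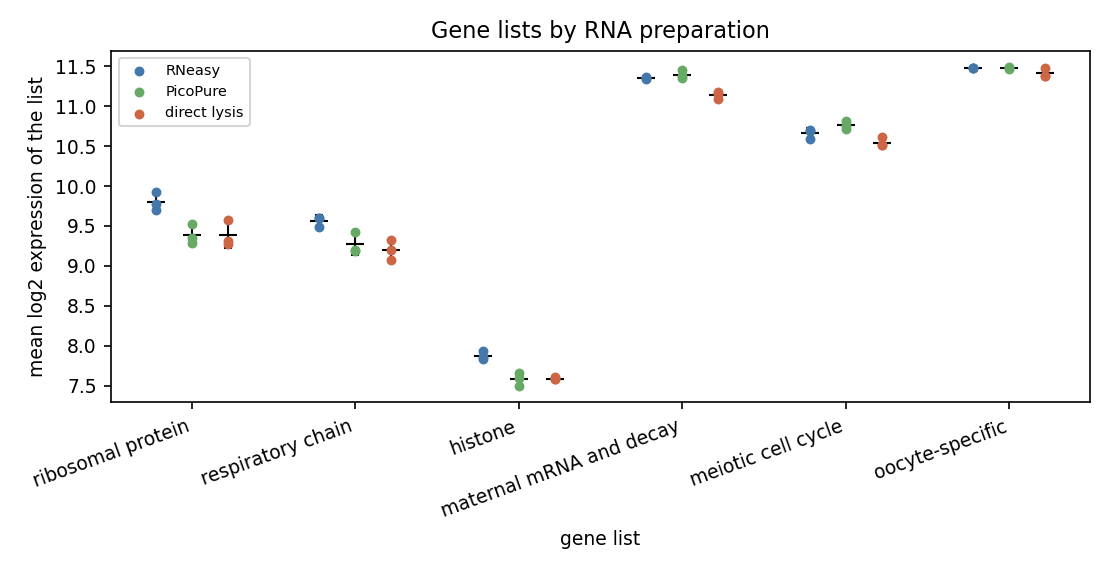
Mean log2 expression of 6 gene lists (vertical axis, not starting at 0) on each array, by list (horizontal axis) and RNA preparation (colour). Points are single oocytes, horizontal bars are means and error bars are the SD of 3 oocytes. Ribosomal protein genes averaged 9.80 with RNeasy, 9.38 with PicoPure and 9.38 with direct lysis, and oocyte-specific genes 11.48, 11.48 and 11.41.

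Small RNA and background groups had small negative medians with PicoPure. Under a further quantile normalization the small nuclear and nucleolar, microRNA and keratin lists were not called, and with fry the microRNA, receptor, keratin and proteasome lists were not. The quantile-normalized medians were -0.10 for small nuclear and nucleolar RNA genes, -0.03 for microRNAs, -0.04 for receptors and -0.05 for keratin, skin and milk protein genes. The keratin list was not called without RNeasy replicate 3 or PicoPure replicate 1. The proteasome list was not called without RNeasy replicate 1 or 2, PicoPure replicate 2 or 3, or direct lysis replicate 2. Of 65 small nuclear and nucleolar RNA genes, 40 of them above background on no array, 52 had a lower value, with a median of -0.15 (adjusted p = 0.0043; adjusted p = 0.144 with an estimated correlation), among them the RNase P RNA gene Rpph1 (-0.98) and the 7SK RNA gene Rn7sk (-0.48). Of 300 microRNA precursor genes, 211 of them above background on no array, 236 had a lower value, with a median of -0.09 (adjusted p = 3.6e-05; adjusted p = 0.247 with an estimated correlation). Mir320 had -0.41 and Mir330 -0.33. The sensory receptors, which mark the background, had a median of -0.11 (adjusted p = 4.0e-10; adjusted p = 0.43 with an estimated correlation), and keratin, skin and milk protein genes -0.08 (adjusted p = 0.0116; adjusted p = 0.712 with an estimated correlation). The proteasome genes had a median of -0.10 (adjusted p = 0.0481; adjusted p = 0.144 with an estimated correlation), with Psma6 at -0.63 and Psmd2 at 0.53. No member of these 5 lists passed, over all genes or adjusted over the list alone.

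Meiotic cell cycle genes had a small positive median, whose call was lost in 7 of 16 alternatives: the filter on level, quantile normalization, values raised to background, fry, an estimated correlation, and without RNeasy replicate 3 or PicoPure replicate 1. Of 52 members 34 had a higher value with PicoPure, with a median of 0.07 (adjusted p = 0.0097; adjusted p = 0.144 with an estimated correlation; 3 higher and 1 lower adjusted over the list alone). The spindle gene Tpx2 had 0.40 ± 0.07 SE (adjusted p = 0.177), the separase gene Espl1 0.94, the kinesin gene Kif20a 0.46 and Birc5 -0.39. The other 9 lists were not called. Their adjusted camera p was 0.706 for oocyte-specific genes, 0.145 for maternal mRNAs and decay factors, 0.302 for cumulus genes, 0.25 for blood genes, 0.957 for oviduct genes, 0.302 for mitochondrially encoded genes, 0.478 for immediate early genes, 0.145 for reference genes and 0.742 for zygotic genome activation genes. Adjusted over the list alone, 1 gene was higher in the list of maternal mRNAs and 1 among the reference genes. For oocyte-specific, oviduct, reference and zygotic genes the median, the mean and camera's direction did not share 1 sign, with medians of -0.01, -0.03, 0.01 and 0.01.

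Direct lysis was also set against each kit. Against RNeasy 33 genes were higher and 54 lower, and against PicoPure 34 were higher and 85 lower (limma). Cks2 was lower in both, by -3.66 (adjusted p = 0.0129) and -3.59 (adjusted p = 0.0104), as were Dcun1d5 (-2.83 and -2.78) and Il7 (-2.08 and -1.80). n-R5s136 differed by -0.13 from RNeasy (adjusted p = 0.747) and was higher by 1.74 than with PicoPure (adjusted p = 0.0104). Fth1 was lower by -0.66 than with RNeasy (adjusted p = 0.0495) and differed by 0.33 from PicoPure (adjusted p = 0.243). Over the 3 preparations 127 genes differed (moderated F). With only the arrays of the groups compared, limma called 3 genes against RNeasy and 0 against PicoPure, where 2158 had an unadjusted p under 0.05. Under a further quantile normalization the share of higher genes moved from 37.9% to 49.4% against RNeasy and from 28.6% to 42.5% against PicoPure. Against RNeasy the count was 3, 16 and 17 without RNeasy replicates 1, 2 and 3, 25, 16 and 39 without PicoPure replicates 1, 2 and 3, and 54 without direct lysis replicate 3. Against PicoPure it was 33, 40 and 34 without RNeasy replicates 1, 2 and 3, and 30, 14 and 44 without PicoPure replicates 1, 2 and 3. Over the 3 preparations it was 4, 28 and 23 without RNeasy replicates 1, 2 and 3, 34, 30 and 47 without PicoPure replicates 1, 2 and 3, and 66 without direct lysis replicate 3.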

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

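The test in this part, Dixon's test for a single array far from the others, was applied to the 6 purified samples together, a choice made after the data were seen. It was run over 62 measures: the detected genes, the 18 list means and the genes named by size or in the oocyte panel. It found 3, about as many as chance alone gives at 1 in 20, so none of them is established as an outlier. The mean of the cumulus and granulosa list was 7.46 in RNeasy replicate 3, with the next sample at 7.19 and the lowest at 7.11. The same array had the fewest detected genes, 9640, and the highest median of the sensory receptors, 5.88. The mean of the maternal mRNAs and decay factors was 11.45 in PicoPure replicate 3, with the next sample at 11.37 and the lowest at 11.34. Gdf9 was 12.80 in PicoPure replicate 2, with the next sample at 12.70 and the lowest at 12.66. Groups of 3 oocytes were not tested in this way, and the 6 purified samples include both kits, which differed in some of these measures.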

How the results depend on the processing

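Crude lysate against purified RNA, fitted with the purified samples as 1 group, an alternative added after seeing the data, gave 223 genes against 201. The alternatives other than single arrays left out and those listed next stayed within 1.5 times each count. With every row of the table tested, which adds rows with no gene of their own, the counts were 443 for crude lysate against purified RNA, 27 for PicoPure against RNeasy, 309 for direct lysis against RNeasy, 198 against PicoPure and 267 over the 3 preparations. A minimum 2-fold difference left 64, 4, 39, 57 and 58, by its construction. A further quantile normalization gave 73 genes for direct lysis against PicoPure and 81 over the preparations. It gave 158 for crude lysate against purified RNA, of which 136 were among the 201. PicoPure against RNeasy fell from 12 genes to 0 with trended and robust variances (limma, 1595 at an unadjusted p under 0.05), to 0 with only the arrays compared (1730), and was 51 with array weights. With only the arrays compared, direct lysis gave 3 genes against RNeasy and 0 against PicoPure (2158 unadjusted), where fewer samples give fewer degrees of freedom. For crude lysate against purified RNA all arrays are compared already, so that setting does not differ there. Otherwise the cause was not tested.

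With a replicate block, the counts were 25, 0 (1549 unadjusted), 15, 17 and 14. The numbers are shared by the labels. The deviations of same-numbered oocytes correlated at -0.09 to 0.13, and those of differently numbered oocytes of other preparations at -0.11 to 0.17. Most samples, but not all, correlated best with an oocyte of their own number. The correlations are weak and do not settle whether the numbers pair the samples.

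With each array left out in turn the counts ran from 24 to 232 (crude lysate against purified RNA), 0 to 15 (PicoPure against RNeasy), 3 to 95 and 14 to 123 (direct lysis against RNeasy and PicoPure) and 4 to 96 (3 preparations). Called lists ran from 1 to 6 and from 7 to 9. The difference in detected genes between direct lysis and RNeasy, 952, ran from 694.5 to 1245, and was 813 with a permutation p of 0.0321 at the 99th percentile of the receptors, 753.7 (p = 0.182) at the 90th, 149 (p = 0.0786) with the filter on level and 76.3 (p = 0.557) with the median of all genes as the level. The difference in median SD between direct lysis and PicoPure ran from -0.00219, without direct lysis replicate 2, to 0.0735, and an SD of 2 values has a lower median than one of 3 by construction. The 5 lists called for crude lysate became 1 with the filter on level, 1 with quantile normalization, which was the sensory receptors used as background, 0 with an estimated correlation and 2 with fry. The 9 called for PicoPure became 5 with quantile normalization, 0 with an estimated correlation and 4 with fry. Of the 30 named genes called for crude lysate, 6 kept their call in each alternative tried (Cks2, Dcun1d5, Il7, Mir99b, Olfr1029 and Vmn2r-ps104), and of the 12 for PicoPure 0 did. No called gene or list reversed its direction past the threshold. Signal near the background level limits what can be said of the weakly expressed genes higher in crude lysate.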

Other observations

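The tests in this part chosen only after the result was seen were those of normalization by level, of other cells in the purified samples, of a single crude lysate, of chance agreement between oocytes and of a difference shared by most genes. Some genes differed far more between oocytes than between preparations. Malat1, a nuclear long noncoding RNA, was 11.70 in RNeasy replicate 3 and 11.29 in direct lysis replicate 3, and between 6.03 and 8.12 on the other 7 arrays. Hormad1, a meiotic chromosome axis gene, was 4.44 in PicoPure replicate 1 and 8.66 to 10.38 on the other 8. These genes were picked for their spread after their values were seen. Beyond the named genes, 13767 rows had no gene or several, and 230 of them passed the test between crude lysate and purified RNA when every row was tested, 119 higher and 111 lower.

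A set of genes was high in 1 oocyte of each preparation: RNeasy replicate 2, PicoPure replicate 1 and direct lysis replicate 2. Slc14a1, a urea transporter gene, was 10.91, 11.48 and 11.46 there and 6.77 to 6.88 on the other 6 arrays. Gdpd3 was 10.21, 11.19 and 11.01 there, and 5.81 to 6.51 elsewhere. Septin3 was 10.73, 10.47 and 10.83, and 7.04 to 7.51 elsewhere. Rnu3a, Phf11d, Ogfrl1, Arl15 and Smim20 shared the pattern and Wdr41 was lower in the same 3 oocytes. These genes were chosen after their values were seen. Of 27 ways to take 1 array per preparation, this choice set 9 genes apart by at least 2-fold, and the next best 2. Shuffling each gene's replicates within the preparations gave at most 5 genes for the best choice in 200 shuffles, which argues against chance agreement of unrelated oocytes, though shuffling treats genes as independent. Over all genes the deviations of the 3 arrays correlated at 0.10, 0.13 and 0.17. Every gene that set them apart by any gap was then left out, which kept 12240 of 12881 genes above background on at least 1 array. The correlations were then 0.033 to 0.10. Leaving out genes on which the arrays agree lowers them by construction. The test therefore does not decide whether most genes of these arrays share a difference. A candidate explanation is a shared mouse or a variant carried in this outbred strain, which the labels do not allow to be tested, so the pattern stays a hypothesis.

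The ribosomal protein, respiratory chain and histone genes had a median difference of -0.27 between PicoPure and RNeasy over 167 genes. Random lists of matched level had a median of 0.01, so normalization that depends on level does not account for it. Nor does 1 RNeasy array, since the median was -0.21 to -0.25 with each RNeasy array left out in turn, although the respiratory chain list by itself was not called without RNeasy replicate 2. Short transcripts remain open: 285 other expressed protein-coding genes spanning under 2000 bp had a median of -0.042, below all matched lists, but this is far smaller than -0.27. Genomic span is only a stand-in for transcript length, and a biological difference between the oocytes or mice of each group was not tested. RNeasy was the group set apart, since direct lysis, which used no column, lay nearer to PicoPure. With RNeasy, PicoPure and direct lysis, ribosomal protein genes averaged 9.80, 9.38 and 9.38. The averages were 9.56, 9.27 and 9.20 for respiratory chain genes and 7.88, 7.58 and 7.59 for histone genes.

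For the genes lower in crude lysate, genomic span is argued against: their median was 29196 bp, against 28318 bp for lists of matched level. The length of the mRNAs was not available and stays untested. Testing all genes again without replicate 1, 2 or 3 of direct lysis gave 164, 91 and 91 lower genes, so no single crude lysate was needed to find lower genes. Only 84, 66 and 65 of these were among the 133, so many of the 133 calls were lost without 1 lysate. The test does not separate dependence on that lysate from the fewer degrees of freedom, and a single lysate stays open for those genes. Other cells in the purified samples stay open. The cumulus and granulosa list differed by 0.044 ± 0.078 (SE), but 22 of its 38 members were above background on no array, and abundant members such as Rgs2 (12.48 in crude lysate, 12.43 in purified RNA) would hide a small share of other cells. Incomplete release or amplification of some mRNAs in the lysate, and the mice behind each group, remain untested.

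Whether chance can account for the counts was asked by regrouping the 9 arrays. For crude lysate against purified RNA, 1 of 100 splits drawn, the real one, reached 201 genes. The highest other, with 121, kept the same crude lysates and mixed the kits. Over the 3 preparations, 1 of 100 splits reached 127 genes, with the highest other at 12. Both results argue against a chance division of the arrays. They do not exclude it, because regrouped arrays carry the real differences in their spread, which lowers their counts. Oocytes that share a mouse would also not be exchangeable. The pairwise comparisons allow 10 splits each, too few for a share under 0.05, and the real and highest other counts were 12 and 1 for PicoPure against RNeasy, 87 and 0 for direct lysis against RNeasy, and 119 and 1 for direct lysis against PicoPure. For gene lists, chance is not excluded between crude lysate and purified RNA, since 32 of 100 splits gave at least 5 lists and the highest other gave 8. Between PicoPure and RNeasy the 10 splits are too few, with 9 lists in the real split, 1 such split, and 5 in the highest other.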
